A study of Homo sapiens with 4 samples.

How the data were processed

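Chromatin of MIA PaCa-2 cells, an established epithelial line from a pancreatic carcinoma, was examined by ChIP-seq of the linker histone variant H1.2. Cells had received a scrambled siRNA (siControl) or an siRNA against ING3 (siING3) at 50 nM, with a repeat transfection 24 h later and chromatin isolation after a further 24 h, per the labels. Each condition had 1 H1.2 immunoprecipitation and 1 input of 2%, so the series held 4 libraries. The chromatin was cut enzymatically, per the labels. There was 1 library per group, and no test between conditions was possible. Every p-value printed compares the reads of 2 libraries, not the conditions.

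The submitters' processing notes name BWA 0.7.9a, Picard 1.115, SAMtools 0.1.19 and HOMER 4.7, without giving their roles. These notes name the builds hg38 and hg19. Coordinates are taken as hg19, because a position on chromosome 1 lies past the end of that chromosome in hg38 and the unplaced sequences carry hg19 names. Peaks were called separately in each immunoprecipitation against its own input, per the file headers, which have the layout of a HOMER peak list. No libraries were pooled.

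The deposited lists give for each peak a normalised tag signal, scaled to a fixed library size, and the tag signal of the immunoprecipitation and of the input after the deeper library was scaled down. They also give a fold (ratio) over input, which equals the ratio of both deposited tag columns, and a p-value against input, per the file headers. The deposited score is the peak caller's own score. Fold, p-value and score are the authors' values and were used only to describe, rank or filter peaks within a list. A further deposited column holds the siControl reads in each peak as whole-number counts. The matching deposited column for siING3 is a signal in scaled reads, in which 1 read is worth 0.905. All 9089 siING3 values in both lists were whole multiples of that step within 0.01 reads (100%), so whole reads were recovered. Neither column is corrected for input. The authors' deposited table of differential peaks gives a fold of siING3 over siControl, a p-value, the nearest gene, the distance to its transcription start site (TSS) and a genomic annotation. That table holds 1 direction, higher in siING3, with folds of 4 and above. Its fold treats a peak without siControl tags as 0.5 tags, so such a fold is not a measured ratio.

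Depth is known only indirectly. If the normalised signal refers to a library of 10 M (mega) tags, the default of the named peak caller, the immunoprecipitations held 27.2 M tags in siControl and 28.7 M in siING3. The inputs then held 31.3 M and 28.2 M tags. At individual peaks the depth was about 20 reads, which leaves wide counting intervals. Intervals are 95% and cover counting error only. Those of shares are Wilson intervals, except that weighted shares have a normal interval from the summed variance over windows. Ratios of shares have a normal interval on the log scale, and those of read ratios are exact (Clopper-Pearson).

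Shared peaks were those that overlapped by at least 1 bp. The number was set beside 100 sets of siControl peaks, each peak moved by 100 to 1000 kb in a random direction. A set of shifts of 2 to 5 Mb was added after the data were examined. The log2 ratio of reads was log2((siING3 + 1)/(siControl + 1)), with a pseudocount of 1, and understates the change at peaks with few reads. The 4-fold rule was applied in both directions, to siING3 peaks for higher siING3 reads and to siControl peaks for higher siControl reads, because the authors' table covers 1 direction. This mirrored count, the weighting of shares to chromosomes or windows of 5 or 1 Mb, the clustering of differential peaks and the shuffling of list membership along chromosomes were all chosen after the data were examined. The prediction for the 5 Mb windows was written before their result was seen. Clustering was compared with 10000 random draws of siING3 peaks, and list membership was shuffled 1000 times. For a peak with 0 siControl reads, a lower bound was computed against a floor of 3 counts per library.

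The overlap count and the 4-fold rule were tested on simulated data. The 4821 siControl peaks were set against simulated siING3 lists. There, 1446 planted shared peaks gave a count of 1453, and 0 planted peaks gave 12 overlaps. Of 200 siING3 peaks raised 8-fold among 4268, the 4-fold rule recovered 193 (96.5%), and 154 of 4068 unchanged peaks (3.79%) also passed it. This simulation had no peak calling and leaves out the picking of siING3 peaks for high siING3 reads. Its 3.79% is therefore not the rate of false passes in the real lists.

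The rule for named genes was fixed before the data were examined. It took the 12 differential peaks of largest fold, the 8 of smallest p-value, up to 8 at promoters, the 8 genes with most differential peaks, the 6 peaks of highest score in each list, members of the fixed gene lists with a differential peak, and ING3 and the H1.2 gene. The lists reported were the NuA4/TIP60 complex, the ING family, linker histones, core histones, pancreatic cancer drivers, the cell cycle, epithelial-mesenchymal transition, pancreatic acinar, ductal and endocrine genes, long neuronal genes, long genes outside the nervous system, olfactory receptors, KRAB-type zinc fingers, taken as all symbols that begin with ZNF, protocadherins, HOX genes, ribosomal protein genes, chromatin regulators, and lamina and heterochromatin genes. Of 699 nearest-gene names, 694 matched a RefSeq gene table of the assembly GRCh38.p14, which was used only for names. A further list and a gene are not reported here.

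Gene annotation was used only for the differential peaks. The planned comparison of each list with 10000 random lists was therefore not made, nor was a comparison of annotation between libraries, a correction of read ratios for input, or peaks per Mb. Alternatives covered the threshold of the peaks, the definition of overlap, the pseudocount, the scaling, the distance to the gene and the differential threshold. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.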

Results

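H1.2 was mapped in MIA PaCa-2 cells treated with a scrambled siRNA or with an siRNA against ING3. ING3 is a subunit of the NuA4/TIP60 histone acetyltransferase complex, and H1.2 is a linker histone, a protein that binds nucleosomes at the entry and exit of DNA. The comparison asks where H1.2 was found after ING3 silencing and where it was found without it. Each condition had 1 H1.2 library and 1 input, so no value has a replicate error. The level of ING3 itself was not measured in the files used here.

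Peaks of H1.2 held few reads in both conditions. The authors called 4821 peaks in siControl and 4268 in siING3. A width of 500 bp was found for 87.2% of the siControl peaks (95% Wilson interval 86.2 to 88.1) and 90.3% of the siING3 peaks (89.4 to 91.2). So common a width points to a set region size of the peak caller and does not measure how far H1.2 binding extended. The peaks covered 2.53 Mb in siControl and 2.22 Mb in siING3. A siControl peak held a median of 19 reads (interquartile range 18 to 21) and a siING3 peak 20 (18 to 22). The median fold over input, as the authors' lists give it, was 4.89 in siControl (range 4.03 to 43.7) and 4.66 in siING3 (4.03 to 37.3). Most peaks lay at the bottom of the score range. Scores of 17 or 18 were held by 59.8% of siControl peaks, and scores of 18 or 19 by 61.1% of siING3 peaks.

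The highest-scoring siControl peak, on chromosome 1 from 16957803 to 16958303, held 45 siControl reads. At that site siING3 held 50 reads, or 45.3 after scaling, although the site is not in the siING3 list. A neighbouring peak on chromosome 1, from 16948181 to 16948681, held 34 siControl reads and 34.4 scaled siING3 reads. The other siControl peaks of highest score lay on chromosomes 10, 12 and 16 and held 29 to 32 siControl reads against 13.6 to 22.6 scaled siING3 reads. The highest-scoring siING3 peak, on chromosome 12 from 3725895 to 3726395, held 34.4 scaled siING3 reads and 13 siControl reads. Another siING3 peak of high score, on chromosome 5 from 2179216 to 2179716, held 32.6 scaled siING3 reads and 3 siControl reads. The non-coding gene LOC100506858 was nearest, with its TSS at 133 kb. A further peak on chromosome 12 held 28.1 scaled siING3 reads and 8 siControl reads. Its nearest gene was CACNA1C-IT3, a transcript of the calcium channel locus CACNA1C. The remaining siING3 peaks of highest score, on chromosomes 5, 7 and 12, held 41.6, 30.8 and 27.2 scaled siING3 reads against 15, 16 and 16 siControl reads. Among all siControl peaks, 459 (9.52%, 8.72 to 10.4) held at least 20 siING3 reads, the median of a called siING3 peak. Among siING3 peaks, 81 (1.90%, 1.53 to 2.35) held at least 19 siControl reads.

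The positions of the peaks hardly coincided between conditions. Only 23 siControl peaks (0.477%, 0.318 to 0.715) overlapped a siING3 peak, against a mean of 20.4 (range 10 to 32) when siControl peaks were moved along the chromosome. The overlap was thus not distinguishable from that of shifted positions. At the 23 shared peaks, median reads were 19 in siControl and 18.1 after scaling in siING3. With peaks extended by 5 kb on each side, 554 siControl peaks (11.5%, 10.6 to 12.4) met a siING3 peak, above the range of 336 to 431 in shifted sets.

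**Figure D1:**
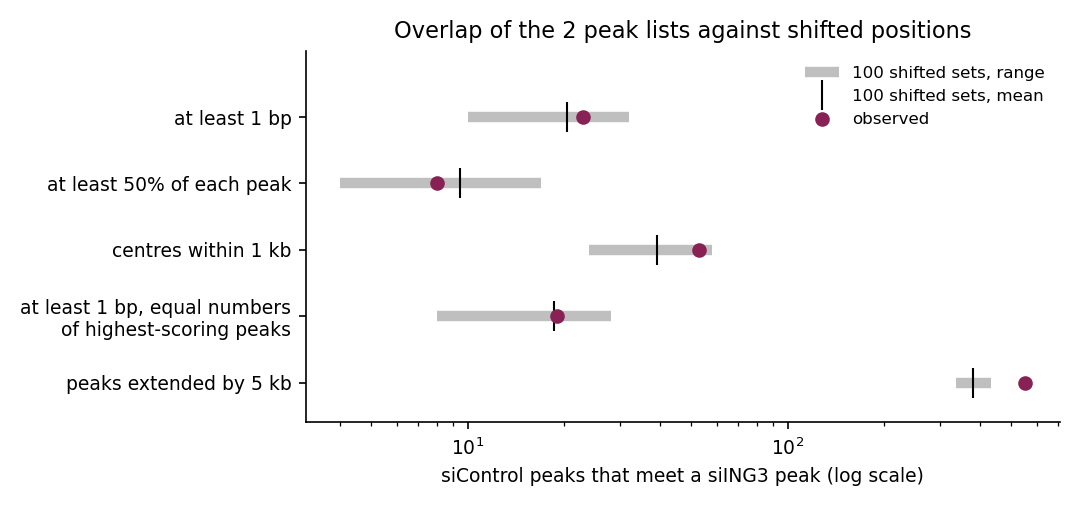
Number of siControl peaks that meet a siING3 peak (horizontal log axis) under each definition of overlap. Dots are observed numbers, grey bars the range of 100 shifted sets and black ticks their mean. The observed 23 overlaps of at least 1 bp lie within the shifted range of 10 to 32, and only the 554 with peaks extended by 5 kb lie above it.

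Each library had more reads than the other at its own peaks. At siControl peaks the median log2 ratio of siING3 over siControl reads was -0.84 (-0.85 to -0.81), and siING3 was higher at 4.38% of them (3.84 to 4.99). At siING3 peaks the median was 1.23 (1.19 to 1.26), and siING3 was higher at 98.5% (98.1 to 98.8). Over all 9089 peaks the median was -0.08. A list chosen in 1 library favours that library, so the sign of each median follows from how the peaks were picked.

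Differences of at least 4-fold were more frequent at siING3 peaks. They were found at 1046 of 4268 siING3 peaks (24.5%, 23.2 to 25.8) in favour of siING3, and at 472 of 4821 siControl peaks (9.79%, 8.98 to 10.7) in favour of siControl. The ratio of these shares was 2.50, and it fell to 1.78 among 500 bp peaks with at least 20 reads. Weighted to 5 Mb windows with at least 5 peaks of each list, the shares were 14.4% (13.1 to 15.8) and 7.78% (7.01 to 8.63). Weighted to 1 Mb windows with at least 3 peaks of each list, they were 6.69% (4.91 to 8.47) and 5.99% (5.14 to 6.97), a difference within the intervals. Such windows must hold siControl peaks, and 6.26% of differential peaks lay within 50 kb of one, against 38.4% of other siING3 peaks, so the choice of windows can itself lower the siING3 share.

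**Figure D2:**
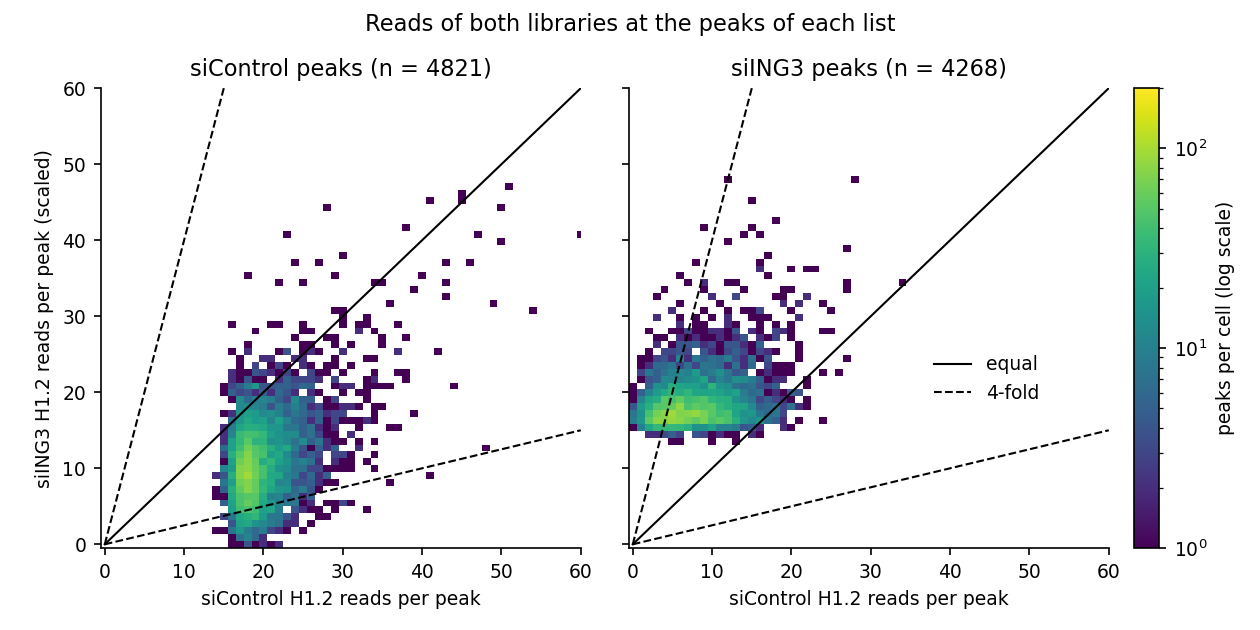
Reads of the siControl library (horizontal axis) and scaled reads of the siING3 library (vertical axis) at siControl peaks (left) and siING3 peaks (right). Colour gives the number of peaks per cell on a log scale, the solid line marks equal reads and dashed lines 4-fold differences. The axes end at 60 reads, which leaves out 1 siING3 peak. Most peaks hold about 20 reads in their own library, and siING3 peaks reach past the 4-fold line more often (24.5%) than siControl peaks (9.79%).

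Both lists had peaks on all 23 chromosomes analysed, and on 9 the counting interval of the ratio of shares left out equal shares. Chromosomes 8 and 18 held a larger share of siING3 than of siControl peaks, by ratios of 2.00 (1.59 to 2.51) and 1.98 (1.46 to 2.68). Chromosomes 5 (1.23, 1.08 to 1.40) and 10 (1.28, 1.07 to 1.53) followed. Shares were lower in siING3 on chromosomes 17 (0.613, 0.523 to 0.718), 22 (0.613, 0.445 to 0.844), 16 (0.731, 0.628 to 0.851), 19 (0.798, 0.670 to 0.951) and 3 (0.811, 0.673 to 0.978). The intervals of the other 14 of 23 chromosomes included equal shares. Of 9060 pairs of neighbouring peaks along a chromosome, 63.3% (62.3 to 64.3) came from the same list. With list membership shuffled within chromosomes this share was 51.0% (range 49.5 to 52.7), and within 5 Mb windows it was 55.6% (54.1 to 57.5). The intervals of the chromosome ratios treat peaks as independent, so with such neighbours they are too narrow. They were also not corrected for the 23 chromosomes, and those close to equal shares carry little weight.

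**Figure D3:**
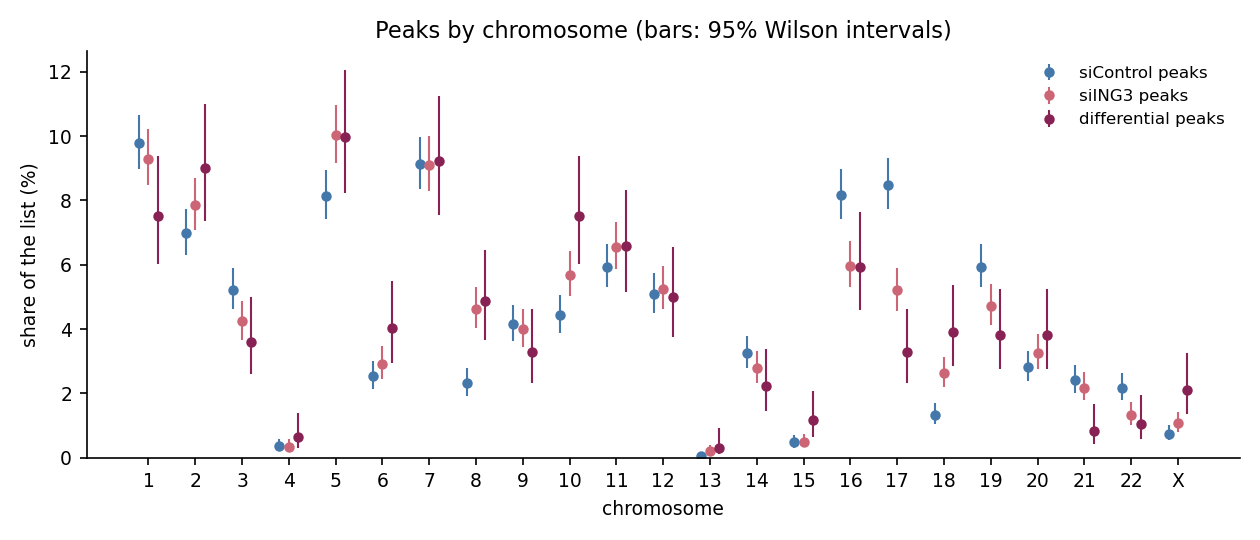
Share of each list on each chromosome in percent, for siControl peaks (blue), siING3 peaks (rose) and differential peaks (purple). Points are shares and bars 95% Wilson intervals. Chromosome 17 holds 8.48% of siControl and 5.20% of siING3 peaks, and chromosome 8 holds 2.32% and 4.64%.

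The authors' deposited table lists 943 differential peaks, all higher in siING3 and all in the siING3 list, of which they make up 22.1% (20.9 to 23.4). The folds in the authors' deposited table range from 4 to 45.5 with a median of 5.69, and its p-values range from 1.29e-28 to 4.89e-06. A differential peak held a median of 20 siING3 reads and 3 siControl reads. After scaling, differential and other siING3 peaks both held a median of 18.1 siING3 reads. Their median siControl reads were 3 and 9. By these medians, few siControl reads rather than more siING3 reads set differential peaks apart within the siING3 list. Of the differential peaks, 25 held 0 siControl reads and 571 held 1 to 3. None of the 943 overlapped a siControl peak. Their median distance to the nearest siControl peak was 754 kb (676 to 817), against 90.3 kb (81.8 to 98.8) for the other siING3 peaks. Differential peaks were picked for few siControl reads, which favours sites away from siControl peaks. Only 23 of all siING3 peaks (0.539%) overlapped a siControl peak. The absent overlap and the longer distance are therefore not separate evidence of a change.

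Differential peaks lay mostly away from promoters. They were intergenic at 526 sites (55.8%, 52.6 to 58.9) and intronic at 369 (39.1%, 36.1 to 42.3), and 12 (1.27%, 0.729 to 2.21) were at promoters. Exons held 14, transcription termination sites 10, 3′ UTRs 8 and non-coding transcripts 4. The median distance to the nearest TSS was 75217 bp (67688 to 82130), and 377 (40.0%) lay beyond 100 kb. Repeats were annotated at 356 (37.8%, 34.7 to 40.9), among them 118 LTR elements, 96 SINEs with 68 Alu copies, and 96 LINEs with 49 L2 and 45 L1 copies. The nearest gene was protein-coding for 573 (60.8%) and non-coding RNA for 338 (35.8%). Gene annotation was used only for the differential peaks. Whether these shares differ from those of other peaks or positions was therefore not tested.

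The peak of largest fold lay in intron 1 of CELF4, an RNA-binding protein that regulates splicing in neurons, on chromosome 18 from 35075475 to 35075975. It held 23 siING3 reads and 0 siControl reads, at least 6.94-fold higher after scaling against a floor of 3 counts. The next lay on chromosome 3 from 115687195 to 115687695 in intron 3 of LSAMP, a neuronal adhesion molecule. Its nearest gene was GAP43, a growth cone protein, with a TSS 345 kb away. This peak held 18 siING3 reads and 0 siControl reads, at least 5.43-fold higher. A further peak with 0 siControl reads lay in intron 7 of WWOX (at least 5.73-fold). Its nearest gene was the transcription factor gene MAF, at 695 kb. Another lay in intron 5 of AUTS2, a gene of neuronal development (at least 5.43-fold). WBSCR17 (now GALNT17), a glycosyltransferase, was its nearest gene at 633 kb. Another with 0 siControl reads lay in intron 3 of TMEM132D (at least 5.43-fold). A site 71.1 kb upstream of SHISA6, a regulator of AMPA receptors, had 0 siControl reads too (at least 5.73-fold). The zinc finger genes ZNF519 (at least 6.04-fold) and ZNF98 (at least 5.73-fold) were nearest to such peaks, at 97.8 kb and 11.5 kb. For FUNDC2P2 (113 kb) and MYADML (19.5 kb) as nearest genes, the bounds were at least 6.04-fold and at least 5.13-fold. The peak with SALL3, a zinc finger transcription factor gene, as nearest gene at 183.5 kb held 22 siING3 and 2 siControl reads. Its scaled ratio was 9.96 (exact interval 2.45 to 87.4). That with LOC102723362 as nearest gene, at 241 kb, held 20 and 1 reads, a ratio of 18.1 (2.90 to 750). The lower bounds at 0 siControl reads set siControl to 3 counts and leave out the counting error of siING3. With that error, the exact lower limits of the ratio ran from 3.74 near MYADML to 5.20 at CELF4. All named differential peaks were picked for high siING3 reads and few siControl reads. The bounds and intervals given for them, here and below, leave this picking out and can overstate the true ratio. The 12 peaks of largest fold have folds of 36.03 to 45.51 in the authors' deposited table. Folds of this size imply 0 siControl tags, although the read counts were 2 for SALL3 and 1 for LOC102723362. Tags and reads of siControl were thus not counted alike. By their folds 20 differential peaks had 0 siControl tags, and 25 had 0 siControl reads.

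Smallest p-values added other sites to these. A peak on chromosome 5, 133 kb from the TSS of LOC100506858, held 36 siING3 and 3 siControl reads. Its scaled ratio was 10.9 (3.43 to 55.1). A peak in intron 1 of AUTS2, on chromosome 7 from 69166834 to 69167506, held 25 reads against 1, a ratio of 22.6 (3.70 to 929). FAT3, an atypical cadherin, was the nearest gene of a peak on chromosome 11 with 27 reads against 1, at a distance of 552 kb. NTF3, which encodes a neurotrophin, was nearest to a peak with 26 reads against 1 at a distance of 17.8 kb. The remaining peaks of this group had the non-coding genes FLJ33360 (25 reads against 1) and LINC01163 (25 against 2) as nearest genes. The TSS of each lay at 385 kb and 56.7 kb.

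At promoters, the largest differences were at RNF180, a ubiquitin ligase, and ADAMTS18, a secreted metalloproteinase. Each held 20 siING3 reads and 1 siControl read, a scaled ratio of 18.1 (2.90 to 750), at distances of 0.469 kb and 0.51 kb from the TSS. The promoter of SPEF2, a sperm flagellar protein, held 19 reads against 2, a ratio of 8.60 (2.08 to 76.1). ST8SIA3, a sialyltransferase, had 22 reads against 3, a ratio of 6.64 (1.99 to 34.6). Promoter peaks at FAM162B, LINC00701 and LOC101929574 held 20, 18 and 17 siING3 reads against 3, 3 and 2. A promoter peak on chromosome 14 held 19 against 3, with MIR539 as nearest gene in the authors' deposited table and MIR889 as the annotated transcript.

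Some genes were the nearest gene of several differential peaks, often at long distances. WBSCR17 and the non-coding gene LOC102723427, both on chromosome 7, were nearest to 12 each. These peaks lay 11.4 to 633 kb from the TSS of WBSCR17 and 90.1 to 775 kb from that of LOC102723427. MAF on chromosome 16 and CALN1, a neuronal calcium-binding protein gene on chromosome 7, were nearest to 7 each. LOC283177 on chromosome 11 had 6, and CELF4, LINC01250 and LOC100506858 had 5 each. Apart from CELF4, these genes lie in the 12 windows of 5 Mb with most differential peaks. On chromosome 7 from 65000001 to 75000000, 39 of 64 siING3 peaks (60.9%, 48.7 to 71.9) were differential. From the first to the last of them, 66978099 to 71937768, a block of 4.96 Mb held 57 siING3 peaks and 0 siControl peaks. In that block the median siING3 peak held 21 siING3 reads and 4 siControl reads. AUTS2 contained 7 of the differential peaks, CALN1 5 and GALNT17 4. The block was picked after the data were examined, and its ends are set by the differential peaks.

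**Figure D4:**
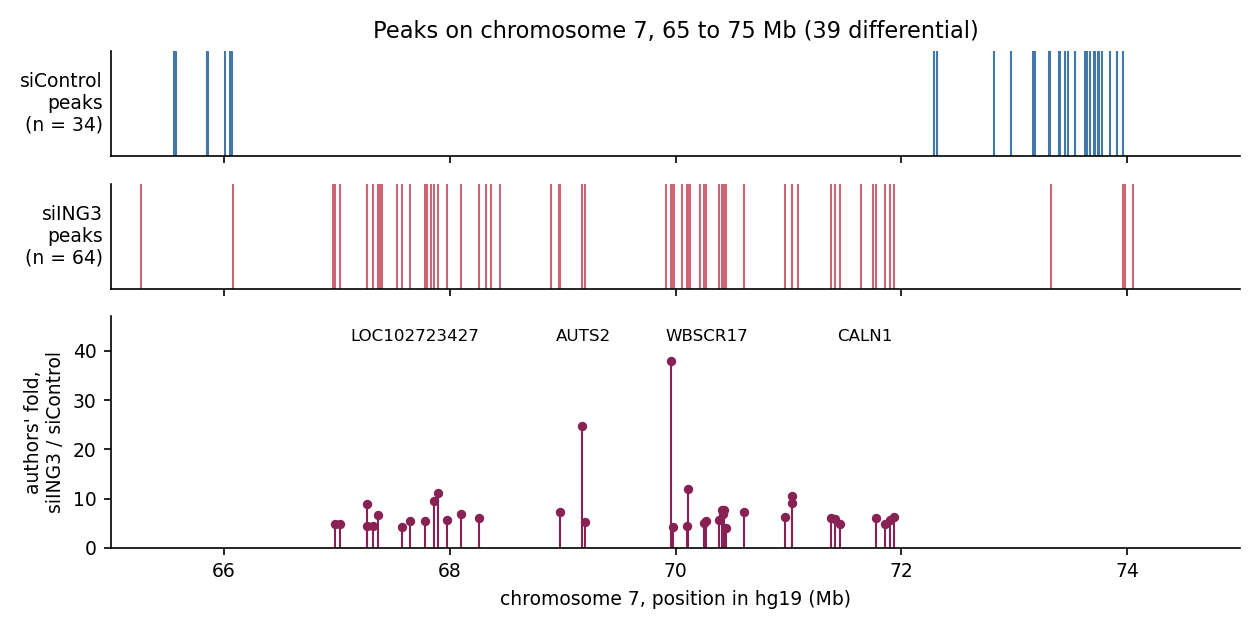
Map of chromosome 7 from 65 to 75 Mb (hg19). Vertical ticks mark the 34 siControl peaks (top) and 64 siING3 peaks (middle), and the lower panel gives the fold of each of the 39 differential peaks in the authors' deposited table. The siControl peaks lie outside the span of the differential peaks, 66978099 to 71937768.

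The other dense 5 Mb windows differed in their siControl peaks. The first 5 Mb of chromosome 2, with LINC01250, the peroxidasin gene PXDN and the neuronal transcription factor gene MYT1L, held 27 siING3 peaks, of which 15 were differential, and 0 siControl peaks. Chromosome 20 from 20000001 to 25000000 held 17 siING3 peaks, 11 of them differential, and 0 siControl peaks. Chromosome 11 from 130000001 to 135000000, with the adhesion molecule genes OPCML and NTM, held 25, 14 and 1. The first 5 Mb of chromosome 5, with the homeobox genes IRX1 and IRX2, had 23 differential peaks among 63 siING3 peaks, and 50 siControl peaks. Chromosome 16 from 80000001 to 85000000, with the cadherin gene CDH13, held 38 siING3 and 40 siControl peaks. The other dense windows, on chromosomes 5, 10, 14, 16 and 19, held 3 to 16 siControl peaks. Together the 12 densest windows held 188 differential peaks (19.9%, 17.5 to 22.6) but 8.83% of siING3 peaks (8.02 to 9.72). These windows were ranked by the differential count itself.

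The gene lists fixed in advance were searched for differential peaks. Of 28 long neuronal genes, 7 were the nearest gene of a differential peak and 10 were nearest or contained one. Of those 7, 2 had their TSS within 100 kb of the peak and 0 within 10 kb. Peaks lay in introns of the netrin receptor DCC (19 reads against 3, ratio 5.73, 1.69 to 30.3), the dystrophin gene DMD (19 against 6, ratio 2.87, 1.101 to 8.769), DLG2 (19 against 4), the neurexin NRXN3 (24 against 6, ratio 3.62, 1.44 to 10.8), CNTNAP2 (20 against 3), MACROD2 (18 against 3) and LSAMP. OPCML (26 against 3), LRP1B (20 against 1) and CDH18 (20 against 2) had intergenic peaks. Of 19 long genes outside the nervous system, WWOX alone was found, with 4 peaks inside it. Among 701 symbols beginning with ZNF, 16 genes were nearest to 21 peaks, 4 of them for ZNF536. ZNF319 had a peak in exon 2 with 30 reads against 4, and ZNF667 had peaks with 31 against 6 and 20 against 2. Of 864 olfactory receptor symbols, OR2AT4, OR2M1P and OR5J2 were nearest to 1 peak each, and OR2L13 contained a peak. Whether these numbers exceed those of random genes was not tested.

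Of 20 genes of the epithelial-mesenchymal transition list, 1 was found: MMP2, a gelatinase, had an intergenic peak at 17.1 kb (22 reads against 3). Of 26 chromatin regulators, 0 were the nearest gene of a differential peak. The counts were 0 for the NuA4/TIP60 complex (18 genes), the ING family (5), linker histones (20 symbols, old and new), core histones (78), pancreatic cancer drivers (20) and the cell cycle (22). They were also 0 for pancreatic acinar, ductal and endocrine genes (22), protocadherins (64), HOX genes (39), ribosomal protein genes (77), and lamina and heterochromatin genes (10). Lists of these sizes can hold 0 by chance, and lists were not compared with each other. ING3 and HIST1H1C, the gene of H1.2, had 0 differential peaks. A gene without a differential peak is not shown to lack a change, since the authors' deposited table holds 1 direction and its own folds of at least 4. By the scaled reads, 74 of its 943 peaks, DMD and NRXN3 among them, lay under 4-fold.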

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

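The 4-fold counts, alternative scalings, their repeat on 500 bp peaks with at least 20 reads, the exact binomial test, the overlap without differential peaks and the addition of host genes were chosen after the data were examined; the rest were fixed before. Of 48 alternatives to 16 results, 24 stayed within 1.5 times a count or within the 95% interval of another value, and 24 moved. Of the former, 5 could not change. No median log2 ratio changed sign. Requiring at least 2 times the smallest fold over input left 419 siControl and 375 siING3 peaks, and p-values of 1e-10 or less left 737 and 538. Shared peaks numbered 8 with 50% overlap of each peak, 53 with centres within 1 kb, 554 with 5 kb extensions and 0 with the higher fold over input. The median log2 ratio at siControl peaks was -0.87 and -0.66 with pseudocounts of 0.5 and 5, -0.90 centred on the shared peaks and -0.78 with the scaling of the differential table. At siING3 peaks these values were 1.27, 0.94, 1.17 and 1.29. Over all peaks that last scaling gave -0.012. Among 500 bp peaks with at least 20 reads, 438 siING3 and 171 siControl peaks passed 4-fold. An exact binomial test on whole reads was one-sided, in favour of each list's own library, with Benjamini-Hochberg adjustment within each list. It called 2375 siING3 and 1247 siControl peaks and compares 2 libraries only. Each list was picked for high reads in its own library, which favours such calls. Raising the differential fold to 1.5 times its smallest value left 461 peaks, and p-values of 1e-10 or less left 359. With a TSS within 10 kb, 5 listed genes were found in place of 28. The smaller counts follow from stricter thresholds, and the 53 and 554 shared peaks from looser definitions of overlap. The other moved values follow from the changed pseudocount, centring, scaling or rule. A filter on a density of at least 5 and the removal of differential peaks that overlap siControl peaks took out nothing, and no shared peak was differential, so these test nothing. Input correction, random lists, annotation by library and genes with peaks in 1 list were not run. A depth of about 20 reads leaves wide counting intervals at single peaks. No paired analysis was possible because each group had 1 library.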

Other observations

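The tests below were chosen after the data were examined. Each was set after its result was seen or could be foreseen, except the weighting to 5 Mb windows, whose prediction was written before its own result was seen. Over the choices tried, shares of 4-fold differences were weighted in 7 ways, and the values differed with the window size. By chromosome the siING3 share was higher on 23 of 23 chromosomes, and by 5 Mb window in 132 of 202. It was higher in 65 of 129 of the 5 Mb windows restricted to 500 bp peaks with at least 20 reads. In 1 Mb windows it was higher in 230 of 848, 146 of 477, 98 of 311 and 47 of 148 with at least 1, 2, 3 and 5 peaks of each list. Windows in which both shares were equal are not counted as higher. In 5 Mb windows restricted to 500 bp peaks with at least 20 reads and at least 3 peaks of each list, the shares were 14.6% (12.2 to 17.04) for siING3 and 9.34% (7.74 to 11.2) for siControl. In 1 Mb windows with at least 1, 2 or 5 peaks of each list, the siING3 shares were 7.71%, 7.34% and 5.73%, against siControl shares of 8.51%, 6.71% and 4.73%, and the intervals overlapped each time.

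Peaks of the conditions overlapped by at least 1 bp no more often than shifted peaks. With peaks extended by 5 kb on each side, the 554 overlaps lay above the shifted range of 336 to 431. They also lay above the range of 262 to 353 for shifts of 2 to 5 Mb. Reads that rose and fell by chance near the calling threshold are a candidate explanation of the low overlap at 1 bp. Among the siControl peaks of smallest p-value, 6 of 964 overlapped a siING3 peak, within the range of 1 to 13 in shifted sets. Relocation of H1.2 after ING3 silencing predicts the same, so this value favours neither. They cannot be told apart, because each condition had 1 H1.2 library and no pair of siControl libraries could be compared.

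Differences of 4-fold were more frequent among siING3 peaks than among siControl peaks. The deposited scaling factors of 0.905 and 0.948 do not account for the excess, since equal shares would need a factor of 0.728 on siING3 reads. Whether another way of scaling would give such a factor was not tested. Calling thresholds did not remove the excess either (ratio 1.78 among 500 bp peaks with at least 20 reads in their own library), nor did weighting to chromosomes (siING3 share 23.5%) or to 5 Mb windows (14.4%). At 1 Mb the siING3 share was 6.69% and within the interval of the siControl share, but those windows need siControl peaks and hold 1834 of 4268 siING3 peaks, so they leave out the regions of fewest siControl reads. Uneven coverage of the libraries at that scale and a regional gain of H1.2 after silencing therefore cannot be told apart.

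Differential peaks clustered. There were 180 neighbouring pairs within 100 kb. Random draws of siING3 peaks gave a mean of 108 (range 74 to 151), and draws within chromosomes 104 (75 to 132). Random placement among siING3 peaks thus did not give as many. Differential peaks were picked for few siControl reads, and the draws took no account of those reads. Regions of low siControl coverage could give close pairs too, so the count favours no cause. A candidate explanation is that H1.2 rose over broad blocks such as that around AUTS2, WBSCR17 and CALN1. Differences between the libraries in base composition or in enzymatic digestion might give the same blocks, and neither was tested because no genome sequence or fragment lengths were used here.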
